A study of Penicillium oxalicum with 6 samples.

How the data were processed

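Total RNA of mycelium from 3 Δku70 and 3 ΔPOX01387 libraries was enriched for mRNA, fragmented, reverse transcribed with random primers and sequenced on the BGISEQ platform, per the labels' protocols. The labels' protocols do not describe a strand-marking step. The submitters' processing notes name BWA 0.7.10-r789, Bowtie2 2.1.0, RSEM 1.2.12 and DESeq2, with no statement of which step each served. The genome build, the annotation and any filters are not given in the sources used here.

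The authors deposited 1 table per library with a gene ID and an FPKM value, per the file headers. FPKM is a fragment count scaled for transcript length and for the number of mapped fragments, and the deposited values carry at most 2 decimals. Raw or expected counts were not used here. The values were therefore analysed on a log scale and no count model was fitted. The depth per library is unknown in absolute terms, and no counting intervals or detection limits are given. Relative depth was checked on the low values, where FPKM moves in steps of 1 read. Among genes listed at 0 in at least 1 library, the share whose low value equalled the smallest step of any library was between 59.0% and 73.8% per library, within 5% plus 0.01 FPKM and among values under 2.5 steps. Small differences in the value of a read, read as the median of ratios between 0.9 and 1.1 to Δku70 replicate 1, were removed first; that median cannot show a larger difference in depth.

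Groups and replicate numbers were taken from the sample titles. FPKM values were transformed to log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which kept 8925 of 9727 genes and left out 802. The strains were compared with limma 3.58.1 in R 4.3.3, using an intensity trend for the prior variance, two-sided tests and Benjamini-Hochberg adjustment over the tested genes, at a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale and understate the changes of weakly expressed genes. Genes that share reads with near-identical copies or overlapping neighbours could not be recognised, so single-gene values carry that uncertainty.

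Simulated data for 8925 genes took the observed means and the moderated spreads of the limma fit. The procedure was tested on them with 200 genes changed. It called 19.1% of the genes changed by 0.5 on the log2 scale, 81.8% of those changed by 1 and 100% of those changed by 2, and 4.32% of its calls were false. With no gene changed limma made 0 calls, with 406 genes at an unadjusted p under 0.05. The simulated spread was drawn independently for each gene, so these rates do not cover genes that vary together between libraries. The adjustment also depends on the share of genes changed. With 200 genes changed in the simulation and 4272 called in the data, these rates do not carry over to the real comparison.

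The rule for the genes named in the text, set before the data were examined, was the deleted gene POX01387 plus, where nothing pairs the IDs with names or products, the 2 largest increases and 2 largest decreases among genes past the threshold whose libraries do not overlap between strains. The block POX01168 to POX01183, genes named within it or beside it, and the neighbours of POX01387 fall outside that rule and were chosen after their values were seen. A total of 22 gene lists had been fixed in advance, 20 defined by product descriptions and 2 by IDs recalled from work on this strain. None was tested, because the files pair no ID with a name or product. The reference table used (assembly ASM172317v3, strain HP7-1) gives locus tags without gene names. None of the 9727 IDs matched it exactly, and 9528 shared a number with one of its protein-coding locus tags. Whether equal numbers mean equal genes was checked with the FPKM steps, since the smallest nonzero FPKM of a weakly expressed gene should fall with gene length. Across 496 genes the Spearman correlation with the length of the equally numbered gene was -0.037, within the range of -0.14 to 0.12 given by shuffled lengths, and simulated data with correct lengths gave -0.96. The table was therefore not used to name or place any gene.

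Stretches of consecutive IDs were defined as at least 3 successive numbers, all past the threshold and changed at least 2-fold in one direction, with an absent or untested number ending a stretch. They were compared with 10000 permutations of the order of the tested genes. The alternatives tried were pseudocounts of 0.1 and 5, no filter on low values and a minimum mean of 5 FPKM, rescaling each library to an equal sum, median-of-ratios scaling, quantile normalization, a prior variance without trend and a robust one, the replicate number as a block, and leaving out each library in turn. Leaving out the 100 most abundant genes was added after the data were seen. The replicates were compared before averaging. No 2 libraries were identical, and the closest pair, ΔPOX01387 replicates 1 and 2, had equal values for 248 tested and untested genes and a median absolute log2 difference of 0.12.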

Results

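The transcriptome of mycelium was measured in 2 strains of Penicillium oxalicum, a filamentous fungus that secretes enzymes degrading plant cell walls. The parental strain, Δku70, lacks a subunit of the Ku complex that joins broken DNA ends, a background in which targeted gene replacement is efficient. The mutant, ΔPOX01387, additionally lacks the gene POX01387. Both strains were grown in glucose medium for 24 h at 28 °C, and about 1 g of mycelium was then moved to medium with Avicel, a microcrystalline cellulose, for a further 24 h. Each strain was represented by 3 libraries sequenced on the BGISEQ platform. The labels do not say whether the libraries came from separate cultures, so the p-values below measure the spread between these libraries, which may be partly technical.

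Each library listed FPKM values for 9727 genes. Between 180 and 209 genes were listed at 0 in the Δku70 libraries and between 253 and 259 in the ΔPOX01387 libraries. The total number of reads is unknown, because the values were deposited as FPKM. Weakly expressed genes moved in steps of 1 read, and each library held the smallest step seen in any library for between 59.0% and 73.8% of its genes near the floor, so a library at a fraction of the others' depth was not seen. The 25 most abundant genes of each library took between 16.4% and 17.5% of its summed FPKM in Δku70 and between 19.7% and 22.3% in ΔPOX01387.

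The first principal component of the log2 values separated the strains and held 74.4% of the variance. The second held 12.2% and set Δku70 replicate 1 apart from the other 2 parental libraries. Spearman correlations across tested genes ranged from 0.968 to 0.986 between parental libraries, from 0.982 to 0.992 between mutant libraries, and from 0.909 to 0.946 between strains. These correlations are across genes, which are not independent replicates.

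**Figure D1:**
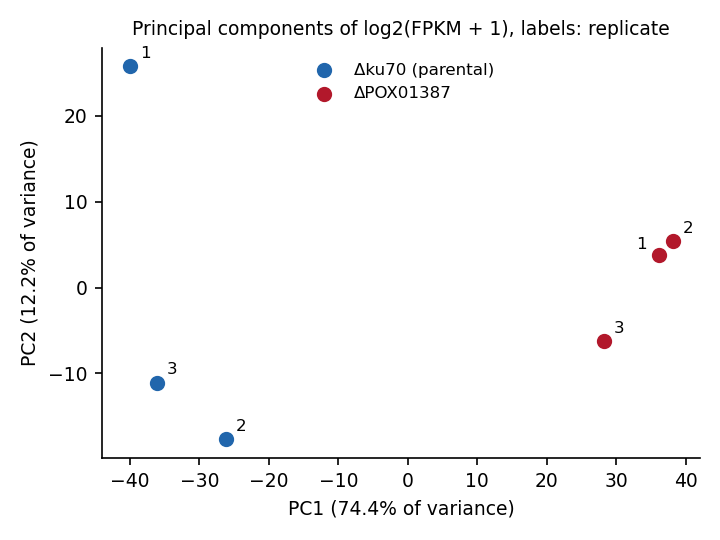
Principal components of log2(FPKM + 1) over the tested genes, with PC1 (74.4% of the variance) on the x axis and PC2 (12.2%) on the y axis. Each point is 1 library, coloured by strain and labelled with its replicate number. The strains lie on opposite sides of PC1, and Δku70 replicate 1 lies apart on PC2.

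POX01387, the gene deleted in the mutant, was examined first in every library. It was expressed weakly in the parental strain, at 9.4, 6.89 and 6.14 FPKM in Δku70 replicates 1, 2 and 3. It was listed at 0.02 FPKM in ΔPOX01387 replicate 1 and at 0 in replicates 2 and 3. The fitted log2 fold change was -3.06 ± 0.18 (SE; limma, adjusted p = 1.3e-04). This value is on the log2(FPKM + 1) scale, which understates the change of a weakly expressed gene. The level of POX01387 followed the strain labels in 6 of 6 libraries.

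The comparison of the strains asked which genes change in expression when POX01387 is missing from mycelium exposed to cellulose. Loss of POX01387 was accompanied by a broad change of the transcriptome. Of 8925 genes with a mean of at least 1 FPKM, 4272 differed between the strains at an adjusted p under 0.05 (limma, two-sided), 1366 of them higher and 2906 lower in ΔPOX01387. The number of higher genes was 868 without Δku70 replicate 3, 830 without ΔPOX01387 replicate 1 and 898 without ΔPOX01387 replicate 2. A change of at least 2-fold was found for 928 genes, of which 321 were higher and 607 lower. With a pseudocount of 5 in place of 1 these were 612 genes, of which 385 were lower. Changes of 10-fold or more were mostly decreases, with 31 genes lower and 3 genes higher. This count is on the log2(FPKM + 1) scale and misses weakly expressed genes. POX01387 itself was 8.31-fold lower on it and is not among the 31. The predominance of decreases among all calls depended on how the libraries were scaled. With the deposited FPKM the median log2 fold change of all tested genes was -0.15, and 68.0% of calls were lower in the mutant. With median-of-ratios scaling the median was 0.01, and the calls split into 2117 higher and 1972 lower. The corresponding split of changes of at least 2-fold was 446 higher and 436 lower. The excess of 10-fold decreases was present under both scalings, with 26 genes lower and 3 higher after median-of-ratios scaling. Of these lower genes, 10 of the 31 and 8 of the 26 belonged to 1 block of consecutive IDs described below.

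The largest increases were those of POX06754 and POX07269. POX06754 rose from 4.87 ± 1.98 FPKM in Δku70 to 141.1 ± 19.5 FPKM in ΔPOX01387 (SD, n = 3 each), a log2 fold change of 4.65 ± 0.27 (SE; limma, adjusted p = 1.1e-04). POX07269 rose from 20.8 ± 10.8 to 345 ± 167 FPKM (SD, n = 3 each), a log2 fold change of 3.96 ± 0.53 (SE; limma, adjusted p = 0.0020). The mutant libraries varied widely for POX07269, with 442.4 and 439.4 FPKM in replicates 1 and 2 and 152.2 FPKM in replicate 3.

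The largest decreases were those of POX08890 and POX05360, both strongly expressed in the parental strain. POX08890 fell from 899 ± 609 FPKM in Δku70 to 4.70 ± 1.21 FPKM in ΔPOX01387 (SD, n = 3 each), a log2 fold change of -7.11 ± 0.45 (SE; limma, adjusted p = 1.5e-04). The parental spread came mainly from replicate 1, at 1589 FPKM, against 439.7 and 666.8 FPKM in replicates 2 and 3. POX05360 fell from 607 ± 113 to 7.59 ± 0.66 FPKM (SD, n = 3 each), a log2 fold change of -6.13 ± 0.14 (SE; limma, adjusted p = 2.0e-05).

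**Figure D2:**
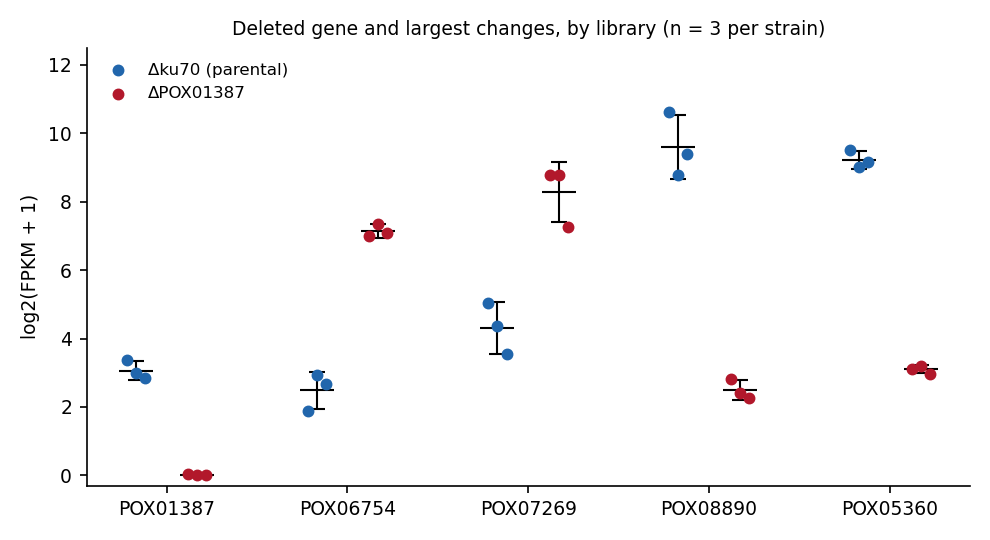
Expression of the deleted gene, the 2 largest increases and the 2 largest decreases, as log2(FPKM + 1) on the y axis. Points are single libraries coloured by strain, and horizontal bars with whiskers give the mean and SD of 3 libraries. The 4 genes with the largest changes were chosen among those whose libraries do not overlap between strains.

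Genes at all levels of abundance differed. Among the 1757 genes with a mean between 1 and 10 FPKM, 153 were higher and 520 lower in the mutant. Among the 5479 genes between 10 and 100 FPKM, 808 were higher and 1931 lower. Among the 1529 genes between 100 and 1000 FPKM, 372 were higher and 422 lower. Of the 160 genes with a mean of at least 1000 FPKM, 33 were higher and 33 lower. These splits are of the deposited FPKM, and the median log2 fold change differed between the classes, at -0.20, -0.17, -0.01 and 0.14 from the least to the most abundant. A near loss of transcripts was rare by the limits used here. There were 6 genes with at least 10 FPKM in every parental library and below 1 FPKM in every mutant library, and 0 genes with the opposite pattern. Another 5 genes had at least 1 FPKM in every parental library and were listed at 0 in every mutant library, and 1 gene had the opposite pattern. POX01387 met neither definition, at 6.14 to 9.4 FPKM in Δku70 and 0.02 FPKM in ΔPOX01387 replicate 1.

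A block of 16 consecutively numbered genes, POX01168 to POX01183, fell together in the mutant. The block was singled out after its values were seen. Its members had a median log2 fold change of -3.50, a median decrease of 11.3-fold, and ranged from -4.08 for POX01178 to -1.44 for POX01183. Of its members, which each changed at least 2-fold by the definition of the block, 10 were lower by 10-fold or more. The block was among the strongly expressed parts of the parental transcriptome, with 7 members at a mean of at least 1000 FPKM in Δku70 and 0 in ΔPOX01387. POX01176, its most abundant member, fell from 4298 ± 708 to 371 ± 49.4 FPKM (SD, n = 3 each). The block took 1.90% ± 0.34 of the summed FPKM in Δku70 and 0.169% ± 0.014 in ΔPOX01387 (SD, n = 3 each). No test is given for these shares, because the members were chosen for their decrease. Below the block, POX01167 had a log2 fold change of -0.35. Above it the decrease continued past the 2-fold limit that defines the block, with -0.86 for POX01184, -0.60 for POX01185 and a median of -1.24 for POX01186 to POX01188, which formed a separate stretch of 3 genes. The block kept 16 members lower by at least 2-fold under each of 3 other scalings.

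**Figure D3:**
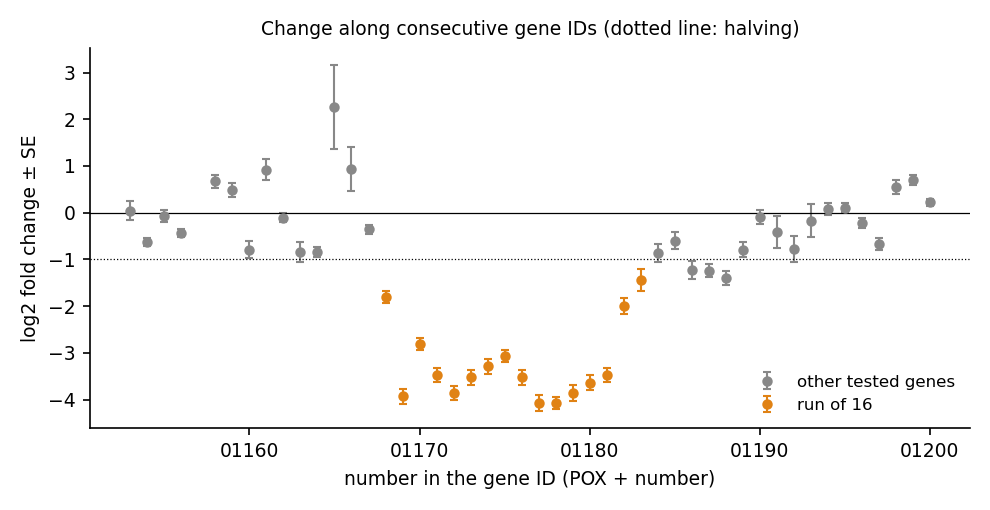
Log2 fold change of ΔPOX01387 over Δku70 (y axis, points with SE from limma) along the numbers of the gene IDs (x axis). Orange points are the 16 genes from POX01168 to POX01183, which lie below the dotted line at a halving by definition. Grey points are the other tested genes on either side.

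Consecutively numbered genes changed together more often than a random order of the IDs gives. Counting unbroken stretches of at least 3 consecutive IDs that all changed at least 2-fold in one direction, 28 stretches held 114 genes. Permuting the order of the tested genes 10000 times gave a median of 7 and at most 33 genes in such stretches (one-sided permutation p = 1e-04, the smallest these permutations can give). Decreases made up 21 stretches with 93 genes, and increases made up 7 stretches with 21 genes. All 8 stretches of at least 5 genes were decreases with the deposited FPKM. With median-of-ratios scaling 26 stretches were found, 16 of decreases with 71 genes and 10 of increases with 31 genes. The log2 fold changes of consecutive IDs correlated at r = 0.27 across genes, against at most 0.042 in permuted orders (one-sided permutation p = 1e-04). The longest stretch had 16 genes, against at most 6 in permuted orders (one-sided permutation p = 1e-04). These 3 statistics were computed as one family, each with a Benjamini-Hochberg adjusted p = 1e-04, on an ordering chosen after the data were seen. Permuting the order also breaks up any variation between libraries that consecutive IDs share. The permutation p-values therefore do not separate such shared variation from a clustered difference between the strains. The ID numbers are taken here as an order only, and positions in the genome were not used.

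**Figure D4:**
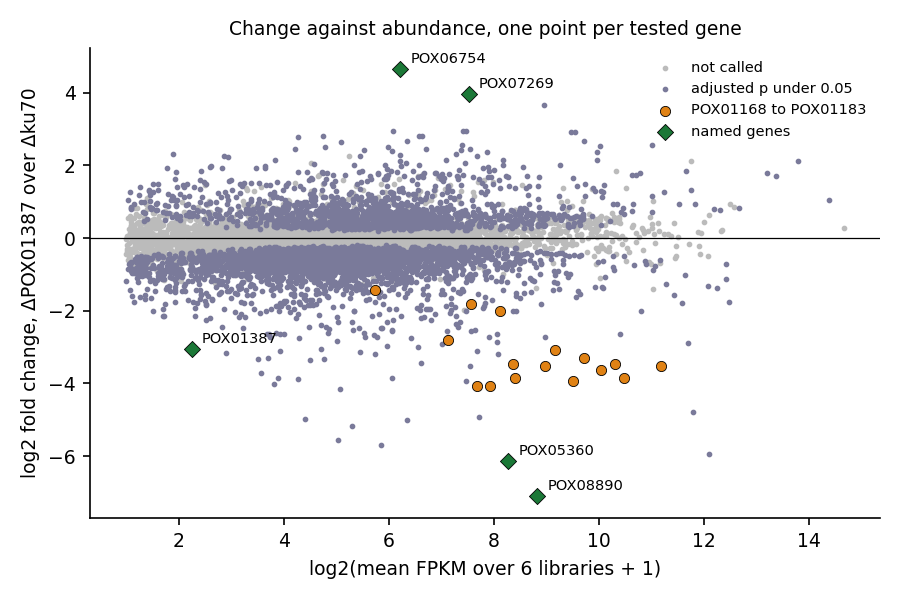
Log2 fold change of ΔPOX01387 over Δku70 (y axis) against log2 of the mean FPKM over 6 libraries plus 1 (x axis), with 1 point per tested gene. Dark points passed an adjusted p under 0.05 in limma, orange circles are POX01168 to POX01183, and green diamonds are POX01387 and the 4 genes with the largest changes. The 16 orange circles all lie below 0.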

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

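The fit without the 100 most abundant genes and all tests of the block POX01168 to POX01183 were chosen after the data were seen. The 5 single genes kept their direction and their side of the threshold under every alternative run for them. The number of differing genes ranged from 2960 to 4585, against 4272. With 1 library left out it was between 2960 and 4002. Leaving out 1 library moved the genes higher in ΔPOX01387 to between 830 and 1345, against 1366. The count was 868 without Δku70 replicate 3, 830 without ΔPOX01387 replicate 1 and 898 without ΔPOX01387 replicate 2; fewer libraries entered these fits, and the cause was not tested beyond that. Without Δku70 replicate 1, the library set apart on the second component, 3890 genes differed, and 3622 of the original calls were kept in the same direction. Median-of-ratios scaling raised the genes higher in the mutant to 2117, which follows from its shift of the median log2 fold change from -0.15 to 0.01. It lowered the share of lower calls from 68.0% to 48.2%, and quantile normalization lowered it to 50.7%, with 1905 genes higher and 1963 lower. Of the original calls, 3338 and 3269 were kept under these scalings. A pseudocount of 5 reduced the genes changed at least 2-fold from 928 to 612 and those at least halved from 607 to 385, since a larger pseudocount shrinks the fold changes of low values. POX01387 lay between -6.13 and -1.31 on the log2 scale over all alternatives, with adjusted p from 8.1e-05 to 0.0016 in limma. The lowest and highest log2 values came from pseudocounts of 0.1 and 5. With a minimum mean of 5 FPKM the gene was not tested. Of the 16 genes in the block, 14 were called at least halved without the 100 most abundant genes, which removed the other 2, and 16 under each other alternative. The labels do not say whether the replicate numbers pair the samples, and the values leave it open. Deviations from the strain means correlated at 0.088, 0.27 and 0.54 between libraries numbered 1, 2 and 3. Pairs of unlike number between the strains ranged from -0.52 to 0.097. Each library correlated best with its own number except Δku70 replicate 1, which was closest to ΔPOX01387 replicate 2, at 0.097. With the replicate block 4585 genes differed, against 4272 without it. The planned runs on counts could not be made, because the values are FPKM, and the planned gene list tests had no members to test.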

Other observations

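The tests in this part were chosen after the results they bear on were seen, except the median-of-ratios scaling and the rescaling to equal sums of all genes, which were planned. In addition to the block described above, 7 stretches of at least 5 consecutive IDs fell by at least 2-fold in ΔPOX01387 with the deposited FPKM. The strongest by median were POX09716 to POX09720, with a median log2 fold change of -3.14, and POX07619 to POX07623, with -2.98. The mean levels of POX09716 to POX09720 had a median of 25.7 FPKM in Δku70 and 1.07 FPKM in the mutant, and those of POX07619 to POX07623 had 112.9 and 10.7 FPKM. Each of the 7 was weaker in the parental strain than POX01168 to POX01183, whose members had a median of 781 FPKM. The closest was POX01690 to POX01695, with a median of 672 FPKM. With median-of-ratios scaling 4 decreasing stretches of at least 5 genes were found in place of 8.

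Genes numbered POX01168 to POX01183 fell together. A random order of the ID numbers is argued against, since the longest stretch in 10000 permuted orders had 6 genes. Loss of this stretch of DNA from the mutant strain is argued against too, since the lowest value of any member in any mutant library was 20.98 FPKM, while the deleted gene was at 0.02 or 0. A single outlying library is argued against, because 16 members were called at least halved whichever library was left out. An effect of the loss of POX01387 on these genes, the difference that the design names, stays open as untested, and so does a second genetic change in the mutant strain. Whether consecutive IDs are neighbours in the genome was not checked.

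POX01386, numbered directly below the deleted gene, rose from 3.79 ± 0.61 FPKM in Δku70 to 32.7 ± 9.4 FPKM in ΔPOX01387 (SD, n = 3 each), a log2 fold change of 2.78 ± 0.22 (SE; limma, adjusted p = 4.0e-04) and higher in 3 of 3 mutant libraries. Only 0.123% of tested genes rose as much. That share counts rises only, a direction taken after POX01386 was seen to rise. Decreases larger than this rise were more frequent, with 31 genes lower by 10-fold or more. The share therefore cannot decide whether a change this large among the 10 IDs nearest to POX01387 arose by chance. Further below, POX01385, POX01383 and POX01382 had log2 fold changes of 0.71, 0.61 and -0.60 and were not called, and POX01384 was too weak to be tested. POX01385 was itself weak, at a mean of 0.93 FPKM in Δku70 and 2.12 FPKM in ΔPOX01387, with libraries that did not overlap between strains. POX01388, numbered directly above the deleted gene, did not rise, with a log2 fold change of -0.31 ± 0.11 (SE; limma, adjusted p = 0.053). Further above, POX01390 rose by 1.64 ± 0.54 (SE; limma, adjusted p = 0.044), with libraries that overlapped between strains. POX01389, POX01391 and POX01392 had 0.11, 0.12 and -0.33 and were not called. An effect of the replaced locus on both sides therefore stays open. An effect of the inserted marker, on 1 side or on both, may account for the rise of POX01386. Regulation by the product of POX01387 may do so too, and no value here separates these. This reading assumes that consecutive IDs are neighbours in the genome, which was not checked.

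Decreases made up 68.0% of calls with the deposited FPKM. A larger share of FPKM in a few abundant genes of the mutant could lower the other genes, but with the 100 most abundant genes left out and the rest rescaled to equal sums the median log2 fold change was still -0.139. Rescaling alone gave -0.18, so the removal accounted for part of the shift and not for all of it. Median-of-ratios scaling gave 48.2% of calls lower, an outcome that the centring itself fixes, so a real excess of decreases and a scaling effect cannot be told apart for all calls, nor for those of at least 2-fold, of which 446 were then higher and 436 lower. The excess of decreases of 10-fold or more, 31 against 3, was 26 against 3 after that scaling. The block POX01168 to POX01183 supplied 10 of the 31 and 8 of the 26.

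Δku70 replicate 1 differed by at least 2-fold from the mean of the other 2 parental libraries for 371 tested genes, against 260 for replicate 2 and 102 for replicate 3. Among the 160 genes with a mean of at least 1000 FPKM, 22 were at least halved and 4 at least doubled in replicate 1. Replicate 2 had 2 halved and 11 doubled, and replicate 3 had 3 halved and 2 doubled.

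Splitting the 6 libraries into 3 and 3 in the 10 possible ways gave the real split 4272 differing genes and 928 differing by at least 2-fold, and the highest other split 0 for both counts (limma). At an unadjusted p under 0.05 the real split gave 5031 genes and the highest other split 458. The real split was the only 1 of the 10 with counts as large, and 10 splits are too few for a share under 0.05. Each other split mixed both strains in both groups, so the difference between the strains entered its spread and lowered its counts. The contrast therefore does not show how many genes would be called by chance.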
